A study of Mus musculus with 8 samples.

How the data were processed

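Gene expression was measured in mouse embryonic footpad skin on 8 two-colour Agilent microarrays. The footpads came from C57BL6 embryos with a conditional knockout of Dicer (KO), the enzyme that cuts precursor RNAs into mature microRNAs, or from wild-type embryos (WT), at embryonic day 16.5 (E16.5) or 17.5 (E17.5). Each of the 4 groups had 2 arrays, and per the labels each array held RNA pooled from 3 to 5 embryos. On every array the footpad RNA carried Cy3 and a universal mouse reference RNA carried Cy5, with no dye swap, so the ratio Cy3 over Cy5 has 1 direction throughout. The 8 arrays lay on 2 slides of 4 arrays, 1 slide for each stage. KO and WT were therefore compared within a slide, while stage and slide cannot be told apart.

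Per the file headers the scans were read with Agilent Feature Extraction 9.5.1.1, which gave each spot's mean intensity, local background intensity and quality marks on a linear scale. The same deposited files hold a processed intensity, already background-subtracted and dye-normalized by that program. The authors' series matrix holds log10 values. On the 24641 probes well above background in both dyes on all 8 arrays, each log10 value equalled the log10 ratio of processed Cy3 to Cy5 plus the mean log10 Cy5 over the arrays, to within 0.00016. Its scale, centring and direction are thus known, and the column medians ran from 2.23 to 2.24. All 8 of its columns were matched to a sample.

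The comparison, its test and the alternatives were fixed before the data were examined. Intensities were corrected with the normexp method (offset 50) in limma 3.58.1 under R 4.3.3, fitted on all spots of an array, and loess-normalized within each array with the 1417 control spots at weight 0. Control spots and spots marked as outliers were then left out and repeated spots averaged, which gave 42006 probes of 60 bases. The 29199 probes well above background in Cy3 on both arrays of at least 1 group were tested (69.5%). M, the log2 ratio of footpad to reference, was fitted with 1 mean for each group over all 8 arrays, and with stage and genotype as terms for KO against WT over both stages. The test was limma's moderated test with Benjamini-Hochberg adjustment, and a probe was called changed at an adjusted p under 0.05. With 2 arrays in each group, their number limits the precision.

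The fit of the normexp background departed from the others on 2 arrays. Its mean was -320.75 in Cy3 and -527.71 in Cy5 on KO E17.5 replicate 2, and -7.00 and -26.9 on WT E16.5 replicate 1, against 4.69 to 8.98 in Cy3 on the other 6 arrays. These 2 arrays hold spots with a local Cy3 background of up to 26390 and 1332.5, whereas the highest on any other array was 52. A fit without the spots that Feature Extraction marked as non-uniform in the feature or its local background (269 to 364 of 43451 spots on an array) gave Cy3 means of 4.81 to 9.14 on all 8 arrays. This fit was chosen after the counts of the planned fit had been seen and several settings had been looked at. It is therefore an added alternative. The planned fit stays the reported result, and the counts without the marked spots stand beside its counts because they differ by more than 1.5 times.

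The files name no gene. For all 42006 probes the gene name columns repeat the probe's identifier, and none of these identifiers is in the table of 49997 mouse genes at hand. Probes are therefore reported by identifier and sequence. Dicer1 itself, the gene lists, the search of 3' untranslated regions for microRNA sites and the choices between probes of 1 gene needed names and are not analysed here, so the targeted gene gave no check of the labels. The rule for named items took the largest rises and falls past the threshold with both KO arrays on the same side of both WT arrays, or the smallest p where none passed. It asked for a gene symbol, which no probe has, so it was applied without symbols and limited to 2 that rose and 2 that fell in each comparison.

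The test was checked on simulated data for the 29157 probes measured on all arrays, in 5 runs with 200 probes changed in each. For KO against WT at E17.5 the planned fit recovered 0.80% of 1.25-fold, 25.6% of 1.5-fold, 61.6% of 2-fold and 88.4% of 4-fold changes, with 5.57% of its calls false. Over both stages it recovered 20.4%, 56.0%, 79.2% and 94.8% of these. Without the marked spots (28334 probes) 44.8% of 1.25-fold and 82.0% of 1.5-fold changes at E17.5 were recovered. All these rates describe the simulated data only. In the real data of the planned fit, KO E17.5 replicate 2 correlated with replicate 1 at r = 0.930, against 0.995 without the marked spots. Whether the rates of recovery and false calls hold for the planned fit with this distorted array was not tested.

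Alternatives covered the processed intensities, a normexp offset of 10, Aquantile, median centring, Cy3 alone, the filter on dim probes, the threshold, a trend and robust prior, array weights, the series matrix, the replicate number as a block and leaving out each array.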

Results

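Footpad skin, the hairless skin of the mouse paw in which sweat glands form, was profiled at E16.5 and E17.5 from embryos with and without a conditional deletion of Dicer. The series asks which transcripts depend on microRNAs during sweat gland development after induction. Each of the 4 groups had 2 arrays. Between 62.0% (KO E17.5 replicate 1) and 72.0% (WT E16.5 replicate 2) of the 42006 probes were well above background in the footpad channel. Pearson's r of M across the tested probes was 0.930 to 0.995 within groups, with KO E17.5 replicate 2 in the planned fit distorted as described in the processing. Without the spots marked as non-uniform it was 0.995 to 0.996 within groups, 0.984 to 0.993 between genotypes of 1 stage and 0.951 to 0.980 between stages.

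Among the probes that changed in KO at E17.5, the 2 with the largest differences between genotypes were lower in KO. Z00008117-1 (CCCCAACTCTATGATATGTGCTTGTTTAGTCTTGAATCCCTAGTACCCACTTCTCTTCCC) had a mean M of 4.01 ± 0.05 (SD, n = 2) in WT and 0.07 ± 0.13 (SD, n = 2) in KO. It fell by 3.94 ± 0.18 (SE) on the log2 scale, or 15.3-fold, with a limma adjusted p of 0.012. Z00022648-1 (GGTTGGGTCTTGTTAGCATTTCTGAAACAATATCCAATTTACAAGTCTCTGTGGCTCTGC) had a mean M of 3.84 ± 0.04 (SD, n = 2) in WT and 0.11 ± 0.19 (SD, n = 2) in KO, a 13.2-fold fall with a limma adjusted p of 0.00623. With processed intensities the log2 differences at these probes were -4.85 and -4.37. The largest rises among the probes that changed were smaller. Z00005948-1 (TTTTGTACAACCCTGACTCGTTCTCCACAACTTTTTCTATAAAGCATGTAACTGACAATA) rose 2.28-fold and Z00032319-1 rose 2.19-fold, with limma adjusted p values of 0.0391 and 0.0367.

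In total 34 of 29199 probes changed in KO at E17.5, 5 higher and 29 lower, and 20 of them changed over 2-fold. No probe passed with either KO E16.5 array or either WT E17.5 array left out, where the 4 probes above had limma adjusted p values from 0.113 to 0.47, and none passed in the 4 arrays of E17.5 fitted alone. The count was 2 without either WT E16.5 array, 2 with array weights, where of these 4 probes only Z00022648-1 kept its call, 7 with an offset of 10 or with median centring, where both rises above lost their call, 1087 without KO E17.5 replicate 2 and 14387 without replicate 1. Processed intensities and Cy3 alone, both fixed beforehand as other settings, called 2701 (1201 higher and 1500 lower) and 5063 probes (2539 higher and 2524 lower). The added fit without the marked spots called 4295, 2024 higher and 2271 lower, with a median change of 1.23-fold, and 34 of the 34 planned calls were among them. Leaving out a KO E16.5 array did not alter the E17.5 effects of the 4 named probes (-3.94 at Z00008117-1). That array enters the E17.5 comparison only through the shared estimate of the spread.

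**Figure D1:**
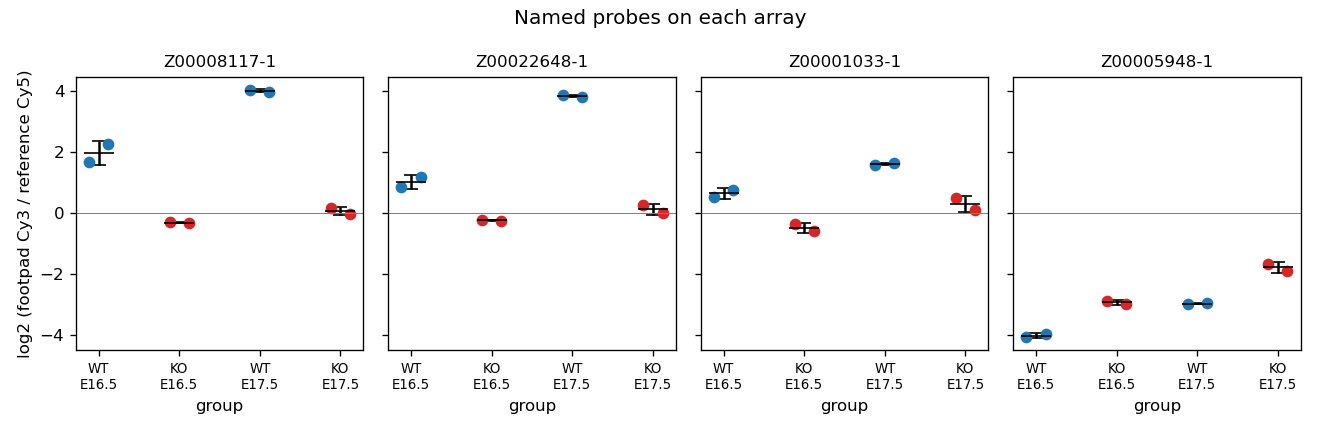
Log2 ratio of footpad (Cy3) to reference (Cy5) signal for 4 probes, with 1 dot for each array, blue for WT and red for KO; black marks show the group mean ± SD (n = 2). In Z00008117-1 the WT mean is 1.97 at E16.5 and 4.01 at E17.5, while KO stays at -0.32 and 0.07; Z00005948-1 is higher in KO at both stages.

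At E16.5 no probe passed the threshold in limma, while 1636 probes had an unadjusted p under 0.05. The probes with the smallest p were measured lower in KO at Z00008117-1 (log2 difference -2.29 ± 0.18 SE) and Z00038833-1 (-1.23 ± 0.10 SE), and higher at Z00005948-1 (1.09 ± 0.10 SE) and Z00018218-1 (0.66 ± 0.08 SE). The limma adjusted p was 0.228 for the first 3 of these and 0.423 for Z00018218-1. Both WT arrays of Z00008117-1 averaged 1.97 ± 0.40 (SD, n = 2) against -0.32 ± 0.02 (SD, n = 2) in KO. The difference at this probe was -4.04 with processed intensities and -1.65 with Cy3 alone. Once the marked spots were left out, 855 probes passed, 315 higher and 540 lower, among them these 4 probes with limma adjusted p values from 0.000358 to 0.00424. Processed intensities called 112 probes, Cy3 alone 1443 and the 4 arrays of E16.5 fitted alone 27. The count was 170 with array weights or without either KO E17.5 array, and 1 without WT E16.5 replicate 2.

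Over both stages 42 probes changed in KO, 12 higher and 30 lower, with a median change of 1.498-fold. Z00008117-1 fell by 3.12 ± 0.34 (SE) on the log2 scale with a limma adjusted p of 0.0322, and Z00001033-1 fell by 1.22 ± 0.11 (SE) with a limma adjusted p of 0.0239. The log2 difference at Z00008117-1 was -4.44 with processed intensities and -2.54 with median centring. Z00005948-1 rose 2.20-fold and Z00002737-1 rose 1.86-fold, with limma adjusted p values of 0.0151 and 0.0286. By the rule that chose them, each of these 4 probes lay on the same side of WT in both KO arrays of both stages. No probe passed with any 1 of the 6 arrays of KO E16.5, WT E16.5 and WT E17.5 left out, where these 4 probes had limma adjusted p values from 0.0801 to 0.219. The count was 2 without KO E17.5 replicate 1, 1698 without replicate 2, 3 with median centring and 2893 with array weights. With median centring Z00005948-1, Z00002737-1 and Z00008117-1 lost their call (limma adjusted p = 0.0893, 0.11 and 0.063), and without KO E17.5 replicate 1 Z00002737-1, Z00008117-1 and Z00001033-1 did (0.0693, 0.108 and 0.0693). In the fit without the marked spots 4566 probes changed, 2267 higher and 2299 lower, including all 42, with a median change of 1.16-fold. Processed intensities called 3212, 1445 higher and 1767 lower, and Cy3 alone 5100, 2601 higher and 2499 lower.

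**Figure D2:**
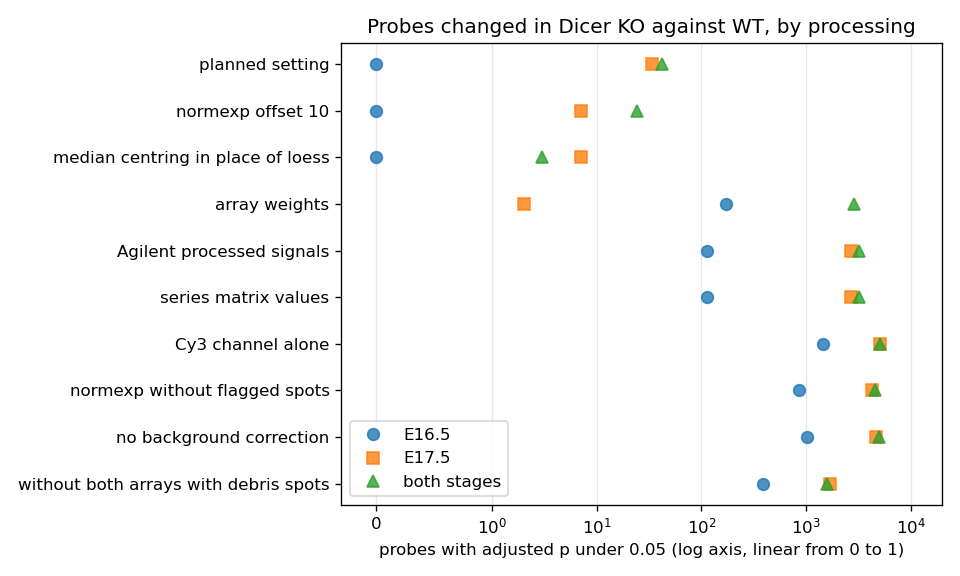
Number of probes called changed in KO against WT (log axis, linear from 0 to 1) in the planned setting and 9 alternatives, for E16.5 (circles), E17.5 (squares) and both stages (triangles). Counts are 0, 34 and 42 in the planned setting and 855, 4295 and 4566 without the marked spots.

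The KO effects at both stages were compared across probes, which are not independent replicates. Pearson's r was 0.18 and Spearman's rho 0.10 in the planned fit. Of the 34 probes called at E17.5, 32 had the same sign at E16.5. Without the marked spots r was 0.56 and rho 0.49, and 227 probes were higher and 436 lower at both stages, against 22.0 and 42.4 for independent lists. Another 3 probes were called in opposite directions. The correlation changed sign to -0.13 when WT E16.5 replicate 2 was left out of the planned fit, and to -0.065 with an offset of 10. It was 0.038 without KO E17.5 replicate 1, 0.48 without KO E17.5 replicate 2, 0.44 without WT E16.5 replicate 1 and 0.086 without KO E16.5 replicate 2.

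The difference of the KO effect between stages was tested directly. No probe passed in limma, with 1558 at an unadjusted p under 0.05. The smallest p values for a lower value at E17.5 belonged to Z00022648-1 (log2 difference of effects -2.45 ± 0.19 SE, limma adjusted p = 0.257) and Z00022485-1 (limma adjusted p = 0.303). The difference at Z00022648-1 was -1.53 with processed intensities. Z00022485-1 was not well above background on any KO array, so its difference of effects has no fixed size. At E17.5 its log2 difference was -1.855 (limma adjusted p = 0.0188), and -2.04 without the marked spots. Its Cy3 level was 3.17-fold lower in KO. Like the other Cy3 ratios of such probes, this is open to dye bias and holds for the planned fit only. Z00012000-1 (1.39 ± 0.17 SE) and Z00058004-1 had the smallest p for a higher value, each with a limma adjusted p of 0.532. The difference at Z00012000-1 was 2.19 with processed intensities. Z00058004-1 was not well above background on either WT array at E17.5, so its difference has no fixed size either. At E17.5 its log2 difference was 1.11 (limma adjusted p = 0.0315), and its Cy3 level was 2.05-fold higher in KO. Without the marked spots this log2 difference was 0.84. Leaving out the marked spots, 89 probes passed, 33 higher and 56 lower. Cy3 alone called 214 and processed intensities 0. The count was 11429 without KO E17.5 replicate 1 and 30 without replicate 2.

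From E16.5 to E17.5, 489 probes changed in WT, 304 higher and 185 lower, and 135 changed over 2-fold. Which direction held more probes depended on the scaling, with 39 higher and 65 lower after median centring, 3572 and 4304 with Cy3 alone and 2611 and 2665 with processed intensities. Z00028697-1 rose by 6.81 ± 0.82 (SE) and Z00037100-1 by 4.87 ± 0.63 (SE) on the log2 scale, with limma adjusted p values of 0.0268 and 0.0308. With processed intensities these rises were 5.64 and 4.21. Z00052819-1 fell by 4.86 ± 0.27 (SE) with a limma adjusted p of 0.00395, and by 2.23 with processed intensities, where the limma adjusted p was 0.0369. Z00026015-1 was not well above background on either WT array at E17.5, which leaves the size of its fall uncertain. Its log2 difference was -4.47 (limma adjusted p = 0.00444). It was -3.40 with Cy3 alone, -3.55 with median centring and -7.33 with processed intensities. The Cy3 ratio of 15.8-fold holds for the planned fit only. The count was 59 without either KO E16.5 array, 17 and 22 without WT E16.5 replicate 1 and 2, 13 and 6 without WT E17.5 replicate 1 and 2, and 5409 without either KO E17.5 array. Both rises lost their call with any 1 of the first 6 of these arrays left out (limma adjusted p from 0.103 to 0.309), and both falls without either WT E17.5 array (0.0508 to 0.0953). With an offset of 10 both rises and the fall of Z00052819-1 lost it (0.0593 to 0.106).

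In KO 241 probes changed from E16.5 to E17.5, 94 higher and 147 lower. Z00030012-1 rose by 2.32 ± 0.16 (SE) with a limma adjusted p of 0.013. Z00028697-1 rose by 6.08 ± 0.82 (SE) with a limma adjusted p of 0.0477 and an SD of 1.87 (n = 2) in KO E17.5, and gave no value in the fit without the marked spots. Its rise was 4.76 without KO E17.5 replicate 1 and 7.40 without replicate 2. Z00052819-1 fell by 5.01 ± 0.27 (SE), or 32.2-fold, with a limma adjusted p of 0.00786. Without the marked spots the fall was 13.5-fold, and with processed intensities the log2 difference was -0.67 and did not pass (limma adjusted p = 0.386). Z00026015-1 was well above background on 1 of 2 KO arrays at E17.5, which leaves the size of its change uncertain. Its log2 difference was -5.75 (limma adjusted p = 0.00553), against -5.07 without the marked spots and -4.28 with processed intensities, where it did not pass (limma adjusted p = 0.0769). The count was 0 without either KO E16.5 array, 13 without either WT E16.5 array, 10 without either WT E17.5 array, 15488 without KO E17.5 replicate 1 and 4334 without replicate 2. Both falls lost their call without either KO E16.5 array (limma adjusted p from 0.123 to 0.142), and both rises with any 1 of the 6 arrays other than KO E17.5 left out (0.0594 to 0.405). An offset of 10 called 63 probes, without Z00028697-1 and Z00052819-1 (limma adjusted p = 0.0905 and 0.0713), and median centring 51. Array weights called 16, 0 higher and 16 lower, without Z00028697-1, Z00030012-1 and Z00026015-1 (0.127, 0.149 and 0.0771). Without the filter on dim probes Z00028697-1 lost its call too (0.0508).

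The stage changes of WT and KO, which share no array, overlapped in 70 higher and 92 lower probes, against 0.98 and 0.93 for independent lists, with 1 in opposite directions. Stage and slide cannot be told apart in these counts. Without the marked spots 7176 probes changed in WT and 8164 in KO, with processed intensities 5276 and 6578, and with Cy3 alone 7876 and 8897.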

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

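The test of the difference between stages was fixed beforehand for the planned fit, Cy3 alone, processed intensities and the series matrix. The other tests here were laid down after the counts with and without the marked spots had been seen, and those for the Cy5 channel alone, the shared WT arrays and the slower progression only after the values they measure, as were the limit to 18 splits, the matching of the Cy5 and footpad correlations by WT array and the separate reading of the fits with and without the marked spots. In the fit without the marked spots 89 probes differed in their KO effect between stages by a test of the difference itself, and with Cy3 alone 214 did, against 0 in the planned fit. Processed intensities and the series matrix, which avoid the distorted background fit, called 0 as well. Of the 89, 55 had the same sign at both stages and a larger effect at E17.5, 3 a larger effect at E16.5 and 31 opposite signs. In 75 of the 89 every group had at least 1 array well above background, and of these 45, 2 and 28 fell into the same 3 classes. Z00022648-1 differed by -2.43 on the log2 scale without the marked spots, with KO effects of -1.33 at E16.5 and -3.75 at E17.5. With processed intensities it differed by -1.53 and did not pass (limma adjusted p = 0.345). Z00022485-1 also passed without the marked spots (limma adjusted p = 0.00019), but was not well above background on any KO array, so its difference has no fixed size.

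Probes changed in KO over both stages were set against regrouping of the arrays. Of the 18 splits of the 8 arrays with 2 arrays of each stage on both sides and the stage term kept, 1 called as many probes as KO against WT, the real one with 42, and the highest of the others called 0 (4566 and 14 without the marked spots). These splits are too few for a share under 0.05, and counting all 34 splits other than that by stage, as first laid down, would add splits that mix 3 arrays of 1 slide with 1 of the other and so are unlike the real one. The split by stage, fitted without the stage term, called 1844 and points to the stage and slide structure of the arrays. The Cy5 reference channel alone called 42 probes and the Cy3 channel alone 5100. By stage, Cy5 alone called 10 probes at E16.5 and 58 at E17.5. Cy5 carried reference RNA only, so its calls do not come from the genotype of the footpads. The far lower Cy5 count argues against hybridisation or scanning differences shared by both dyes as the whole source of the calls with Cy3 alone. It decides little for the planned calls, since M is the ratio of both dyes and shared differences would largely cancel in it. After the trend of M on probe GC content was removed, 95.2% of the planned calls were still called (40 of 42) and the count rose to 138, while without the marked spots 89.3% were still called and the count was 4385 against 4566. A biological effect of the Dicer deletion stays open, as do dissection and litter differences between pools, which were not tested.

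The KO effect was measured as larger at E17.5 than at E16.5. The direct test of the difference called 0 probes in the planned fit, 89 without the marked spots and 0 with processed intensities. With replicate error removed, the SD of the KO effect across probes was 0.18 at E17.5 and 0.11 at E16.5, a ratio of 1.63 as planned and 1.52 without the marked spots. Without the marked spots the lowest ratio with any 1 array left out was 1.30, over the bound of 1.2 laid down for it, and the lowest number called with 1 E17.5 array left out was 1454, over 1.5 times the 855 at E16.5, which argues against replicate spread and a single array as the whole source in that fit. In the planned fit the lowest ratio was 1.44, with no value without either WT E17.5 array, and the number called fell to 0 without either of these arrays or either KO E16.5 array. Without WT E17.5 replicate 1 and 2 the 34 called probes kept a median of 98.96% and 101.04% of their effect while the median SE rose 1.35 times, so these lost calls decide nothing and both explanations cannot be told apart there, and slide and stage remain confounded in both fits.

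The KO effect at E17.5 ran opposite to the change with stage in WT, with a slope of -0.49 across probes, and -0.36 without the marked spots. Part of such a slope comes from the WT E17.5 arrays that both differences share. With different WT arrays in each, the less steep slopes were -0.33 and -0.24 in these fits, so replicate error of shared arrays was not the whole source. A deviation common to both WT E17.5 arrays would still enter both differences with opposite signs, and was not tested. The correlation with the stage difference of the Cy5 reference on the same arrays was -0.065 and -0.16, against -0.27 and -0.46 with the footpad change. It was at most 0.34 times as strong (0.20 without the marked spots). This decides little about a slide difference shared by both dyes, since such a difference would largely cancel in M and a weak correlation could be forecast either way. A slide difference in Cy3 alone remains confounded with stage. Slower progression of KO footpads stays open, since the corrected slope of the stage change in KO on that in WT (0.49 and 1.04 with either WT pair in the planned fit, 0.84 and 0.90 without the marked spots) is nearly the same quantity as the slope above, so a value under 1 supports nothing.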

How the results depend on the processing

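The fit without the marked spots, no background correction, the crossed numbers and leaving out both arrays with debris were chosen after seeing the data; the other settings were fixed beforehand. Counts are given in the order KO against WT at E16.5, E17.5 and both stages, then E17.5 against E16.5 in WT and in KO, then the difference of KO effects between stages, against 0, 34, 42, 489, 241 and 0 in the planned setting. Where the cause is not named, the cause was not tested.

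Settings that avoid the distorted background fit, and Cy3 alone, which keeps it but is quantile-normalized between arrays, called far more probes. Processed intensities called 112, 2701, 3212, 5276, 6578 and 0, and the series matrix, built from them, 112, 2692, 3208, 5266, 6564 and 0. Cy3 alone called 1443, 5063, 5100, 7876, 8897 and 214. Normexp without the marked spots called 855, 4295, 4566, 7176, 8164 and 89, no background correction 1023, 4708, 4998, 7609, 8860 and 110. Leaving out both arrays with debris called 386, 1687, 1578, 4088, 5300 and 89 despite 2 fewer arrays. The correlation of KO effects was 0.18 as planned and 0.42, 0.41, 0.57, 0.56, 0.57 and 0.52 in these 6 settings. Leaving out only the marked spots raised each of the counts, on data in which several settings had already been looked at. Cy3 alone, which kept them in its background fit, and no background correction also called more. Within the planned method the low counts thus depended on the marked spots. Cy3 alone and no background correction change other steps too, so they cannot tell whether these spots were the only source. For the difference of KO effects the count also stayed at 0 with processed intensities and the series matrix.

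Other settings kept the distorted fit. An offset of 10 called 0, 7, 24, 186, 63 and 0, and the correlation reversed to -0.065. Median centring called 0, 7, 3, 104, 51 and 0, and the share of higher probes in the WT stage change moved from 62.2% to 37.5%. At an adjusted p under 0.10 the counts were 0, 259, 325, 1111, 2740 and 0. A trend and robust prior gave 0, 219, 201, 779, 1466 and 0, and array weights 170, 2, 2893, 5485, 16 and 0. A fold over 1.5 left 21 over both stages. The 4 arrays of a stage alone gave 27 at E16.5 and 0 at E17.5. Over both stages the average of the stage contrasts gave 91 and no stage term 0. Both filters on dim probes stayed within 1.5 times of every count, and Aquantile moved nothing, since it leaves M as it is.

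With 1 array left out, the lone array of a group is assumed to vary like the other groups. The counts ran from 0 to 170, 0 to 14387, 0 to 1698, 6 to 5409, 0 to 15488 and 0 to 11429, and the correlation from -0.13 to 0.48. The highest E17.5 count came without KO E17.5 replicate 1, which left the distorted replicate 2 alone in its group. Without KO E17.5 replicate 2 the counts were 170, 1087, 1698, 5409, 4334 and 30.

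As a replicate block, the number gave 0 at each stage, 0 over both and 0 for their difference. In the planned fit, samples with the same number correlated at -0.26 at E16.5 and 0.21 at E17.5 in their deviations. Without the marked spots these correlations were -0.22 and -0.014. No pairing was taken from the numbers. Crossed numbers gave 0 at E16.5, as did the fit without a block, which decides nothing about the pairing. Of 531 values of single named probes under these alternatives, 356 stayed on their side of the threshold, 118 lost it, 57 gained it and 0 reversed. Dicer1, the gene lists, the 3' untranslated region search and the choices between probes of a gene were not run, for want of gene names. Signal over background limits the rest: 62.0% to 72.0% of probes were well above it.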

Other observations

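Among the tests here, the 12 skin microRNAs and the 3 controls were fixed before the data were examined, and their use on probe sequences in place of 3' untranslated regions was chosen afterwards. Probes run in the sense of messenger RNA more often than not, since 6.93% hold the AATAAA polyadenylation signal and 3.36% its reverse complement. Each probe was searched for the 7-base match to bases 2 to 8 of each microRNA, and the GC-adjusted KO effect of the probes holding a match was ranked among all 7-base words.

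The 115 probes with the let-7 match CTACCTC lay 0.055 higher in KO over both stages on the log2 scale, at the 99.8th percentile of 14893 words. The 197 probes with the miR-203 match CATTTCA, a microRNA abundant in differentiating epidermis, lay 0.029 higher, at the 97.8th percentile. The 139 probes with the miR-125 match CTCAGGG lay -0.039 from the rest, at the 2.00th percentile, opposite in direction. In the planned fit 3 of the 12 skin microRNAs stood above the 95th percentile, and 5 of 12 without the marked spots, where let-7 reached 99.9, miR-203 99.6 and miR-17 99.5. Taken by stage, the planned fit had 5 of 12 at E16.5 and 2 of 12 at E17.5. There miR-30 went from the 99.9th percentile at E16.5 to the 11.4th at E17.5, and miR-26 from the 84.6th to the 3.89th. Without the marked spots these falls were smaller, from the 99.8th to the 74.7th for miR-30 and from the 75.8th to the 48.6th for miR-26. In that fit 5 of 12 stood above at each stage. Of the 3 controls not abundant in epidermis, 0 did in either fit. With only 3 words and a cut at the 95th percentile, 0 is the likely count anyway, so this gives no contrast.

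The shifts of let-7 and miR-203 would go with a loss of repression by some epidermal microRNAs, as a hypothesis, while that of miR-125 would not. The forecast for loss of repression by epidermal miRNAs, that over 6 of the 12 skin seeds would stand above the 95th percentile, was not met at 3, nor was the opposite bound of at most 1, so the test leaves it open. A probe covers 60 bases of a transcript, so most sites of a gene were not searched, and probes are not independent replicates.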
